A study of Mus musculus with 6 samples.

How the data were processed

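RNA sequencing was run on 6 subcutaneous tumours grown from G422, a mouse glioblastoma cell line, in Kunming mice, an outbred stock. Tumour cells carried either a short hairpin RNA named for Ngb (shNgb, 3 tumours) or the vector control (shVec, 3 tumours), per the labels. Groups and replicate numbers were taken from the sample titles. The labels call the tumours independent, and whether each came from a separate mouse is not stated, so p-values measure the spread between these tumours. A label field for the cell line carries a different running number in each sample while the source of every sample is given as G422; the source was used.

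Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit. That kit selects polyadenylated RNA and does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Bowtie 0.12.2 and the mouse builds mm8 and mm10 are named in the submitters' processing notes without a role. The counting tool, the annotation and the treatment of reads that map to several places are not given in the sources used here. The authors deposited a matrix of read counts per Ensembl gene ID, which holds whole numbers without normalization, and a table of FPKM values for each sample.

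Gene symbols came from GENCODE M21 (build GRCm38), which named 54409 of the 54532 IDs. The 123 IDs without a symbol held 0.0207% to 0.0269% of the reads of a library and stayed in the tests. In the 11113 genes with more than 50 reads in every library, the deposited FPKM equalled the read count divided by a gene factor and a library factor, with a largest relative deviation of 1e-08. The library factors equalled median-ratio size factors and differed from the read totals by up to 2.38%. In those genes the FPKM values thus compare libraries as scaled counts do, and FPKM values were not used for tests; the other genes were not checked.

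The counts were analysed with edgeR 4.0.16 in R 4.3.3. Low genes were removed with the default expression filter, which kept 15203 genes. Libraries were scaled by TMM (trimmed mean of M values), and the groups were compared with the robust quasi-likelihood F-test. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Standard errors of log2 fold changes (shNgb minus shVec) were derived from the F statistic and intervals are 95% confidence intervals. Levels are CPM (reads scaled to a common library size) with TMM scaling, as mean ± SD.

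The test, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The rule took Ngb, then up to 10 called genes of largest change per direction, and the 5 of smallest p per direction where fewer than 5 were called. It left out unnamed predicted genes and pseudogenes and required a mean of at least 1 CPM. From each list described, it took up to 4 members of smallest p. Genes named outside the rule are said to be chosen after their values were seen.

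The 46 gene lists comprise 28 programs and 18 sets of cell type markers, and 38 had the 5 or more tested members needed for a test. Each was tested with camera, which asks whether members rank differently from all other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the 38 lists. Camera with a correlation estimated for each list and fry, a rotation test of the list itself, were run as alternatives. A list score is the mean over members of log2 CPM (prior count 2) centred on the 6 libraries. Scores were compared by a two-sided exact permutation test, for which 3 against 3 allows no p under 0.1. Some lists share members, such as Pgk1 and Ldha in the hypoxia and glycolysis lists.

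Alternatives were RLE and upper quartile scaling, no filter beyond 1 read, a strict filter of at least 10 reads and 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, glmTreat against a fold of 1.5, adjusted p thresholds of 0.01 and 0.1, and leaving out each library in turn. The default filter was applied again after each omission, with 1 group smaller, so the tested members of a list could differ. A mean with 1 library left out can thus differ from the full mean through its members as well as through that tumour. All 10 splits of the 6 tumours into 3 and 3 were also fitted. Copies of 2 genes were sought with blastn 2.17.0, using the longest protein-coding transcript of each as query and requiring 95% identity over 250 bases.

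The pipeline was tested on simulated counts with the means, library sizes and dispersions of this comparison, with 200 genes changed and 14881 genes tested. Of the genes changed 1.5-fold, edgeR recovered 43.3%, of those changed 2-fold 58.2% and of those changed 4-fold 92.4%, with 8 false calls. DESeq2 recovered 50.7%, 61.2% and 92.4%, with 37 false calls. A hypoxia list shifted by -0.5 (log2) was recovered at a mean of -0.44 and 0 of 37 other lists were called. The simulation drew genes independently of each other, unlike genes in real tumours.

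Read totals were 19630319 to 25620667 per library. No pair of libraries in a group was a duplicate: the chi-square per degree of freedom between their counts was 12.7 to 32.4. Intervals on read counts cover counting error only, since reads without molecular identifiers are not independent molecules.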

Results

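The transcriptomes of 6 subcutaneous G422 tumours were sequenced in a study titled as a knockdown of Ngb, which encodes neuroglobin, an oxygen-binding globin best known from neurons, in a mouse glioblastoma line. Tumours of cells labelled shNgb, a hairpin by its name, were compared with tumours of cells carrying the vector (shVec), with 3 tumours in each group. The description of the design instead names Ngb itself as what the cells received. The sample labels were followed, and the Ngb reads do not settle which was done, so shNgb stands below for the label. The shVec libraries held 22427004, 20005933 and 19630319 reads and the shNgb libraries 21018697, 23913765 and 25620667. Between 22158 and 23303 genes had reads, the 10 most abundant genes took 4.07% to 4.38% of a library and mitochondrial transcripts 1.27% to 1.46%. Correlations of log2 CPM between libraries were alike within a group (mean r across genes 0.984, 6 pairs) and between groups (0.984, 9 pairs).

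Ngb itself was scarce in all 6 tumours. It had 28, 23 and 13 reads in the shVec libraries and 18, 19 and 11 in the shNgb libraries, or 1.03 ± 0.33 CPM and 0.690 ± 0.237 CPM (SD, n = 3 each), and the groups overlapped. Its log2 fold change was -0.59 (SE 0.42, 95% interval -1.55 to 0.37). The edgeR p of this gene, chosen beforehand, was 0.197 unadjusted and 0.9997 adjusted over all genes. A lower level in shNgb tumours was thus not detected with this spread between tumours. The interval runs from a fold of 0.341 to a fold of 1.29. The summed reads, 48 against 64, gave a rate ratio of 0.648 with an exact Poisson interval of 0.436 to 0.957, which covers counting error only and not the spread between tumours. Without shNgb replicate 3 the log2 fold change was -0.33. The gene (ENSMUSG00000021032) lies on chromosome 12 at 87097531 to 87102539, minus strand, in the annotation used here (build GRCm38), and counts cover the whole gene rather than single exons.

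No single gene separated the groups by the edgeR test. Among the genes with the smallest p were Ppp1r15a, which encodes the stress-induced regulatory subunit of the eIF2alpha phosphatase (56.1 ± 10.9 CPM in shVec and 31.9 ± 3.36 CPM in shNgb), and Klf4, a zinc finger transcription factor (56.5 ± 6.71 and 34.2 ± 5.82 CPM). Hk2, the hexokinase that starts glycolysis, stood at 112 ± 9.72 and 83.7 ± 6.58 CPM, and Grem1, a secreted BMP antagonist, at 54.4 ± 3.19 and 36.7 ± 6.72 CPM. Csf3r, the G-CSF receptor of neutrophils, stood at 1.38 ± 0.31 CPM in shVec and 3.55 ± 1.15 CPM in shNgb, and Dock10, a guanine nucleotide exchange factor, at 3.66 ± 0.93 and 7.45 ± 1.48 CPM. All of these are means ± SD of 3 tumours, and in each gene the 3 shNgb values lay on one side of the 3 shVec values.

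Of 15203 genes tested, 0 were higher and 0 lower in shNgb at an adjusted p under 0.05 in edgeR, where the smallest adjusted p was 0.9997. An unadjusted p under 0.05 was reached by 392 genes (206 higher, 186 lower), against 760 that chance alone would give. The groups did not overlap in 558 genes higher and 521 lower in shNgb, 7.10% of those tested, where chance gives 10%. limma-voom called 0 genes, with 428 at an unadjusted p under 0.05. DESeq2, with 477 genes at an unadjusted p under 0.05, called 2 higher and 3 lower. In the simulation it made 37 false calls, against 8 by edgeR, so its calls need caution. DESeq2 was run without the expression filter and gave an adjusted p to 27832 genes, so its 477 cannot be set beside 392 or 760. Its higher genes were Hmgn2, a nucleosome-binding protein (log2 fold change 1.70, DESeq2 adjusted p = 1.92e-08), and Col1a1, a chain of type I collagen (0.85, DESeq2 adjusted p = 0.0443). Its lower genes were the pseudogene Rpl17-ps10 (-1.06, DESeq2 adjusted p = 7.58e-08), Ppp1r15a (-0.82, DESeq2 adjusted p = 0.00284) and Klf4 (-0.73, DESeq2 adjusted p = 0.0231). Rpl17-ps10 is outside the naming rule and was chosen after its values were seen.

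The remaining genes of smallest p, taken by the rule and past no threshold, were Rsrp1, Phactr2 and Smtnl2. In edgeR their log2 fold changes were 0.37 (SE 0.08), 1.36 (SE 0.33) and -1.51 (SE 0.31). Those of Hmgn2, Dock10 and Csf3r were 1.70 (SE 0.28), 1.03 (SE 0.25) and 1.37 (SE 0.34), and those of Ppp1r15a, Klf4, Hk2 and Grem1 were -0.81 (SE 0.15), -0.72 (SE 0.14), -0.42 (SE 0.09) and -0.57 (SE 0.13). The adjusted p of all 10 was 0.9997 in edgeR.

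**Figure D1:**
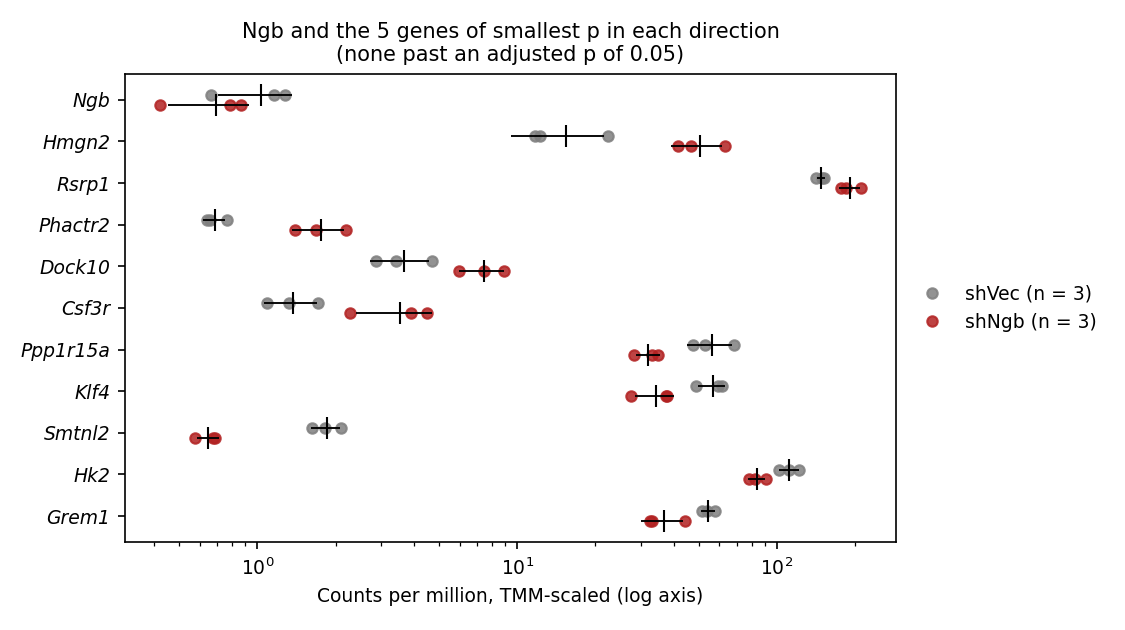
Level of Ngb and of the 5 genes of smallest p in each direction, in TMM-scaled CPM on a log axis. Each point is 1 tumour (grey, shVec; red, shNgb; n = 3 each), ticks are group means and horizontal bars are SDs; the groups overlap for Ngb (1.03 and 0.690 CPM on average) and lie apart for the other 10 genes, of which 0 passed the edgeR test.

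Hmgn2 and Rpl17-ps10 belong to families with near-identical copies, so their own counts are uncertain. Over the 1265 bases of the Hmgn2 transcript, Gm10282 matched 1151 bases at 99.3% identity, and Rpl17-ps10 matched 555 of the 1326 bases of Rpl17, a ribosomal protein gene, at 99.3%. Hmgn2 stood at 15.5 ± 6.03 CPM in shVec and 50.4 ± 11.2 CPM in shNgb, while Gm10282 stood at 93.2 ± 2.07 and 67.7 ± 23.3 CPM. Rpl17 stood at 192 ± 72.7 and 389.7 ± 58.3 CPM, and Rpl17-ps10 at 418.9 ± 67.2 and 201.2 ± 36.2 CPM (SD, n = 3). Summed, Rpl17 and Rpl17-ps10 had a log2 fold change of -0.05 (SE 0.07), and Hmgn2 and Gm10282 0.12 (SE 0.10). Summing Rpl17 with its 14 copies that had reads gave -0.07 (SE 0.06), and Hmgn2 with its 7 copies 0.12 (SE 0.10). The choice of these genes was made after their values were seen.

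**Figure D2:**
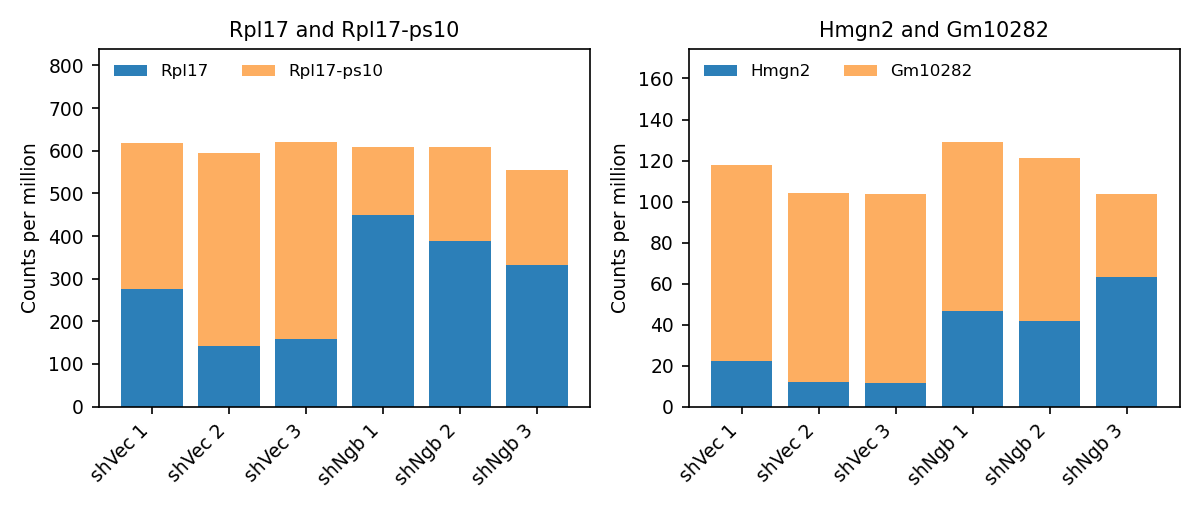
CPM of Rpl17 and Rpl17-ps10 (left) and of Hmgn2 and Gm10282 (right), stacked, in each of the 6 tumours. The parent gene held 24.0% to 44.6% of the Rpl17 pair in shVec and 59.8% to 73.8% in shNgb, and 11.3% to 19.0% of the Hmgn2 pair in shVec and 34.2% to 60.6% in shNgb, while the height of the bars differed less.

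Genes of the hypoxia response stood lower in shNgb tumours. All 25 tested members had a negative log2 fold change, with a median of -0.32. The list passed camera at the preset correlation of 0.01 (camera adjusted p = 2.11e-26). With its estimated correlation of 0.53 it did not pass (camera adjusted p = 0.244). Examples are Vegfa, the main angiogenic growth factor (698 ± 7.08 CPM in shVec, 438 ± 162 in shNgb), Ero1l, an oxidase of protein folding (317 ± 32.2 and 208 ± 49.1), Pgk1 (1418 ± 57.1 and 1183 ± 145) and Ldha (1571 ± 38.1 and 1344 ± 128), enzymes of glycolysis. Vegfa was chosen after its values were seen. The list scores were 0.27, 0.26 and 0.25 in the shVec tumours and 0.12, -0.23 and -0.67 in the shNgb tumours (exact permutation p = 0.1, the smallest possible). Of the 25 members, 0 passed in edgeR over all genes or adjusted over the list alone, and 9 had an unadjusted p under 0.05. Without shNgb replicate 3 the mean log2 fold change went from -0.46 to -0.30.

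The glycolysis list moved the same way, with 17 of 18 members negative, a median log2 fold change of -0.22 and a camera adjusted p of 2.89e-14 (adjusted p = 0.244 with an estimated correlation). Its examples are Hk2, Aldoa (758 ± 18.3 CPM in shVec, 640 ± 67.4 in shNgb) and Eno1 (1886 ± 24.8 and 1628 ± 133). Scores were 0.11, 0.30 and 0.08 in shVec and -0.08, -0.17 and -0.24 in shNgb (exact permutation p = 0.1). Hk2 was the 1 member past 0.05 adjusted over the list alone (edgeR, 0.0301), and 7 had an unadjusted p under 0.05.

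Stress and immediate early genes were lower on average as lists, with overlapping list scores (exact permutation p = 0.2 in each list). Immediate early genes, which are induced within minutes of a stimulus, had 16 of 18 members negative and a median of -0.33 (camera adjusted p = 5.52e-10; adjusted p = 0.244 with an estimated correlation), among them Zfp36 (30.4 ± 5.38 CPM in shVec, 20.6 ± 2.97 in shNgb) and Atf3 (22.5 ± 9.21 and 11.5 ± 1.94). Klf4 alone passed adjusted over the list alone (edgeR, 0.0134). The unfolded protein and integrated stress response had 18 of 25 members negative and a median of -0.13 (camera adjusted p = 5.39e-08; adjusted p = 0.298 with an estimated correlation). Ppp1r15a (edgeR, 0.0099) and Chac1, a glutathione-degrading enzyme (65.2 ± 7.05 and 42.4 ± 8.34 CPM; edgeR, 0.0299), passed adjusted over the list alone. Atf4, the transcription factor of this response, stood at 566 ± 62.2 and 450 ± 29.8 CPM.

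Cholesterol synthesis had 19 of 20 members negative, with a median of -0.29 (camera adjusted p = 1.12e-08; adjusted p = 0.385 with an estimated correlation). The shift of this list rested on individual tumours: its mean log2 fold change of -0.26 became -0.54 without shNgb replicate 1 and -0.09 without shNgb replicate 2. No gene of the list passed adjusted over the list alone in edgeR or had an unadjusted p under 0.05.

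Interferon and antigen presentation genes stood higher in shNgb tumours on average, with a wide spread in both groups. All 30 interferon response members were positive, with a median log2 fold change of 0.77 (camera adjusted p = 6.75e-17; adjusted p = 0.373 with an estimated correlation), for example Mx1 (0.875 ± 0.555 CPM in shVec, 2.49 ± 0.84 in shNgb) and Ifit1 (3.34 ± 1.66 and 7.26 ± 1.74), both antiviral effectors. All 15 MHC class I members were positive (median 0.69, camera adjusted p = 2.65e-09; adjusted p = 0.378 with an estimated correlation), as were all 8 MHC class II members (median 0.94, camera adjusted p = 2.96e-07; adjusted p = 0.370 with an estimated correlation). Of the latter, H2-Ab1 stood at 4.93 ± 1.30 and 18.9 ± 14.2 CPM and Ciita, the class II transactivator, at 2.66 ± 0.81 and 5.12 ± 2.29 CPM. Interferon scores were -0.98, 0.45 and -0.66 in shVec and -0.29, 0.35 and 1.11 in shNgb (exact permutation p = 0.3). Without shNgb replicate 3 the mean log2 fold changes were 0.31 (interferon, from 0.77), 0.21 (class I, from 0.64) and 0.60 (class II, from 1.01), and without shVec replicate 2 those of interferon and class I were 1.36 and 1.05. In these 3 lists edgeR called 0 members adjusted over the list alone, and 2 interferon, 0 class I and 1 class II members had an unadjusted p under 0.05. Scores of T and NK cell markers stood alike, at -0.69, 0.54 and -1.02 in shVec and -0.96, 0.67 and 1.46 in shNgb.

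Markers of immune cells were also higher on average, while the list scores of the groups overlapped. The exact permutation p was 0.4 for T and NK cells, 0.5 for macrophages, 0.2 for B and plasma cells and 0.3 for dendritic cells. The T and NK cell list had all 17 members positive and a median of 1.07 (camera adjusted p = 3.30e-07; adjusted p = 0.414 with an estimated correlation), with Trbc2, a T cell receptor chain, at 0.296 ± 0.366 CPM in shVec and 1.34 ± 0.90 in shNgb, and Nkg7, a cytotoxic granule protein, at 0.597 ± 0.661 and 1.92 ± 1.44. Its mean of 1.03 was 0.36 without shNgb replicate 3, where the call was lost (camera adjusted p = 0.0923), and 1.82 without shVec replicate 2. Those 2 means cover the members that passed the filter in each fit, which may not be the same 17. The macrophage list had 15 of 17 positive and a median of 0.43 (camera adjusted p = 0.000183; adjusted p = 0.452 with an estimated correlation), with Adgre1 at 5.69 ± 2.44 and 10.1 ± 4.75 CPM and Csf1r at 14.7 ± 3.75 and 22.4 ± 9.0. Its call was lost without shNgb replicate 2 (mean 0.25), shNgb replicate 3 (0.17) or shVec replicate 1 (0.15), against 0.38 with all tumours, and the mean was 0.64 without shNgb replicate 1 and 0.65 without shVec replicate 2. The 5 tested B and plasma cell markers had a median of 1.73 (4 of 5 positive, camera adjusted p = 0.00127; adjusted p = 0.244 with an estimated correlation), with Igha, the IgA heavy chain, at 1.14 ± 0.89 and 4.72 ± 3.57 CPM. The 6 dendritic cell markers had a median of 0.30 (5 positive, camera adjusted p = 0.0129; adjusted p = 0.385 with an estimated correlation). Their call was lost without shNgb replicate 2 (mean 0.50) or 3 (0.20), against 0.52 with all tumours, and the mean was 0.86 without shNgb replicate 1. With limma-voom the dendritic call ended (mean 0.48, camera adjusted p = 0.0536). In these 4 lists edgeR called 0 members adjusted over the list alone, and 0 T and NK cell, 1 macrophage, 2 B and plasma cell and 1 dendritic cell markers had an unadjusted p under 0.05.

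Fibroblast and matrix genes were higher on average in shNgb, and the list scores of the groups overlapped. The fibroblast markers had 9 of 10 positive and a median of 0.49 (camera adjusted p = 4.95e-06; adjusted p = 0.298 with an estimated correlation), with Col1a1 at 155 ± 36.0 and 282 ± 72.1 CPM and Col1a2 at 90.5 ± 24.9 and 176 ± 63.2. Their mean of 0.44 was 0.26 without shNgb replicate 1, 0.83 without shNgb replicate 3, 0.74 without shVec replicate 1 and 0.80 without shVec replicate 2. The filter was applied again in each of these fits, so the means may cover different members and do not measure the weight of 1 tumour alone. The fibrillar matrix list, which shares collagens with it, had 13 of 20 positive and a median of 0.15 (camera adjusted p = 0.0023; adjusted p = 0.416 with an estimated correlation), with Bgn, a proteoglycan, at 29.2 ± 7.67 and 52.9 ± 11.1 CPM. That call was lost without shNgb replicate 1 (mean 0.10, against 0.24) or shVec replicate 2 (0.22), and the mean was 0.36 without shNgb replicate 3. With limma-voom the matrix call ended (mean 0.19, camera adjusted p = 0.0536). EdgeR called 0 members of either list adjusted over the list alone, and 3 fibroblast and 5 matrix members had an unadjusted p under 0.05.

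Proliferation genes moved little. Mitosis genes had 29 of 30 positive at a median of 0.08 (camera adjusted p = 1.01e-05; adjusted p = 0.385 with an estimated correlation), with Ccnf, a cyclin of the G2 phase, at 60.3 ± 6.86 and 75.8 ± 5.53 CPM, and their mean of 0.09 was 0.05 without shNgb replicate 3. DNA replication genes had 25 of 30 positive at 0.07 (camera adjusted p = 0.00265; adjusted p = 0.452 with an estimated correlation). The replication call was lost without shNgb replicate 1 (mean 0.07), shNgb replicate 3 (0.03) or shVec replicate 2 (0.06), against 0.07 with all tumours, and the mean was 0.10 without shNgb replicate 2. Cytosolic ribosomal proteins had 43 of 49 negative at a median of -0.05 (camera adjusted p = 0.00123; adjusted p = 0.490 with an estimated correlation), a call lost without shVec replicate 1 (mean -0.04, against -0.06). Adjusted over the list alone, edgeR called 0 members of these 3 lists, and 1 mitosis member had an unadjusted p under 0.05.

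Further programs and the neural list passed camera at the preset correlation. Apoptosis regulators had 24 of 30 positive at 0.08 (camera adjusted p = 0.0129; adjusted p = 0.244 with an estimated correlation), with no overlap of the list scores between groups (exact permutation p = 0.1), and antioxidant and NRF2 targets 16 of 23 at 0.03 (camera adjusted p = 0.0278; adjusted p = 0.452 with an estimated correlation). ERK feedback targets had 12 of 17 negative at -0.09 (camera adjusted p = 0.00822; adjusted p = 0.452 with an estimated correlation) and p53 targets 13 of 19 negative at -0.03 (camera adjusted p = 0.0129; adjusted p = 0.298 with an estimated correlation). The neural progenitor and oligodendrocyte list had 7 of 9 negative at -0.29 (camera adjusted p = 0.00674; adjusted p = 0.244 with an estimated correlation), with Nes, the intermediate filament nestin, at 506 ± 35.3 and 414 ± 28.7 CPM. Calls ended without shNgb replicates 1 or 3 or shVec replicates 2 or 3 for the antioxidant list (means 0.07, 0.06, 0.08 and 0.03, against 0.11), and without shNgb replicate 2 or shVec replicates 2 or 3 for apoptosis (0.12, 0.16 and 0.13, against 0.14). They ended without shNgb replicates 1 or 3 or shVec replicate 2 for ERK targets (-0.09, -0.07 and -0.05, against -0.12, with -0.23 without shNgb replicate 2). For p53 targets they ended without shNgb replicate 2 or shVec replicates 2 or 3 (-0.16, -0.12 and -0.10, against -0.16), and for the neural list without shVec replicate 1 (-0.15, against -0.24, with -0.45 without shNgb replicate 2). Without the low-count filter the antioxidant, p53 and neural calls also ended (means 0.07, -0.02 and -0.06). Adjusted over the list alone, edgeR called 0 members of these 5 lists, and 1 antioxidant, 0 apoptosis, 1 ERK, 2 p53 and 1 neural members had an unadjusted p under 0.05.

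Skeletal muscle markers were lower in shNgb on average, and 1 control tumour stood high. All 8 were negative at a median of -0.86 (camera adjusted p = 0.0038; adjusted p = 0.385 with an estimated correlation), and the score of shVec replicate 2 was 1.40 while the other 5 ranged from -0.68 to 0.14. Acta1, skeletal muscle actin, chosen after its values were seen, had 220 reads in that library and 3 to 57 in the others. Without that library the mean went from -0.90 to -0.07 and the call was lost (camera adjusted p = 0.929). The mean was -1.48 without shNgb replicate 2 and -1.37 without shVec replicate 1. Members passing the filter may differ between these fits. Of the 8 members, edgeR called 0 adjusted over the list alone and 1 had an unadjusted p under 0.05.

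**Figure D3:**
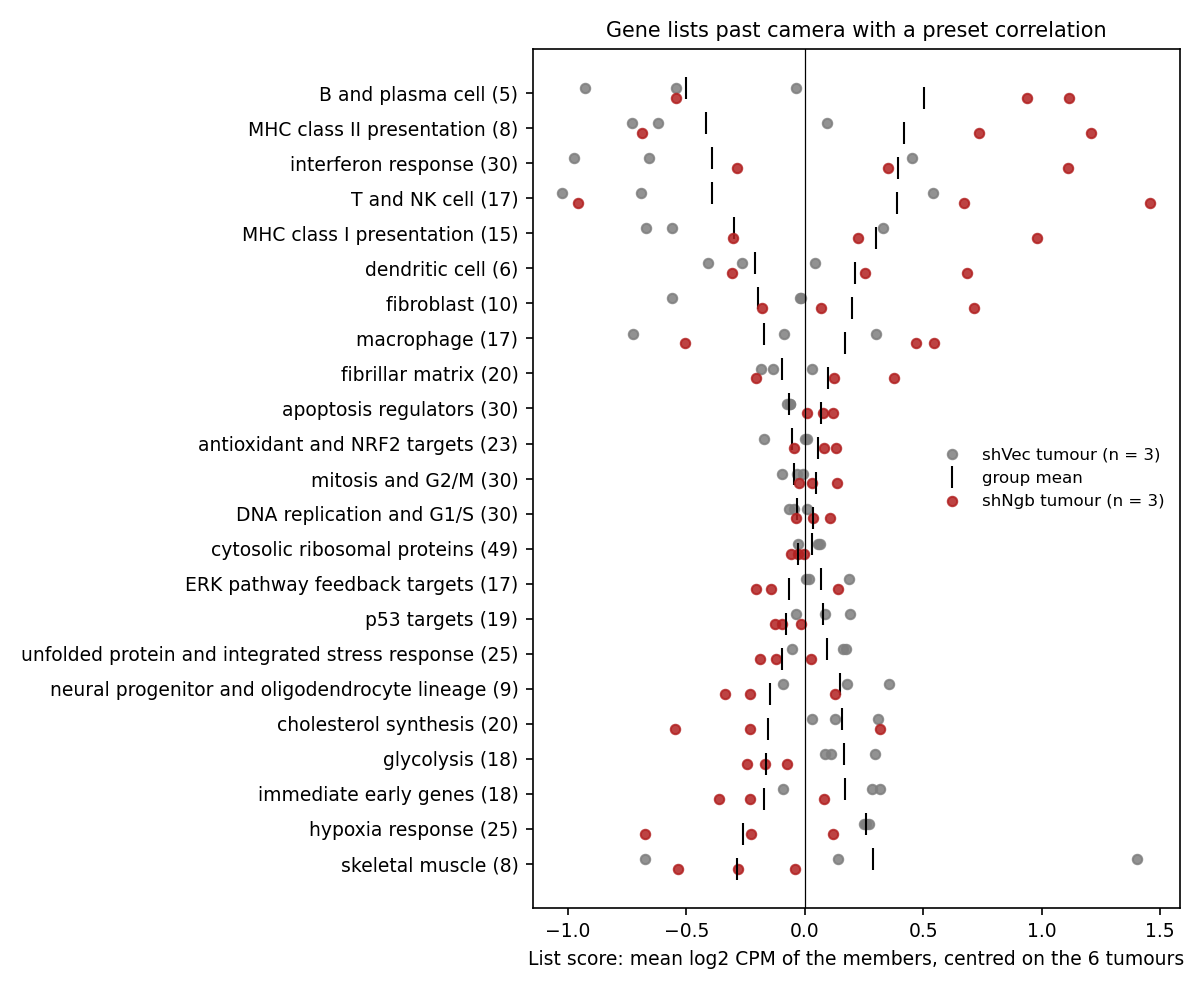
Scores of the 23 gene lists past camera at the preset correlation (tested members in brackets), as mean log2 CPM of the members centred on the 6 tumours. Each point is 1 tumour (shVec in grey, shNgb in red, n = 3 each) and black ticks are group means. The groups lie apart for hypoxia response, glycolysis and apoptosis regulators (exact permutation p = 0.1) and overlap in all other lists shown. Chance alone sets 3 tumours apart from 3 in 10% of cases, and 38 lists were tested, so this separation does not distinguish these lists.

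In all, 13 lists were higher and 10 lower with the preset correlation, and 15 did not pass. With an estimated correlation 0 of the 38 lists passed (smallest adjusted p = 0.244, 6 with an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.453, 3 with an unadjusted p under 0.05). Against the preset 0.01, the estimate was 0.88 for interferon, 0.87 for MHC class I, 0.90 for MHC class II and 0.86 for T and NK cells. It was 0.76 for macrophages, 0.53 for hypoxia and 0.23 for glycolysis, but -0.01 for apoptosis regulators and -0.05 for the neural list. Where the estimate lies far above 0.01, members moved together and camera p-values at the preset correlation overstate the evidence. The unadjusted camera p also rose where the estimate lay below 0.01. It went from 0.00746 to 0.0385 for apoptosis regulators and from 0.00319 to 0.0375 for the neural list. Correlation among members alone therefore does not account for all the lost calls, and a low estimate does not make the preset p-value sound. Over all genes, 0 members of any list passed the edgeR test.

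Of the lists that did not pass camera, receptor tyrosine kinases and their ligands came closest (median -0.07, camera adjusted p = 0.0506), where Hbegf, an EGF receptor ligand, stood at 135 ± 11.9 and 100.4 ± 9.23 CPM and was the 1 member past 0.05 adjusted over the list alone (edgeR, 0.0385). Wnt targets had a median of -0.12 (camera adjusted p = 0.0844), nuclear-encoded oxidative phosphorylation 0.03 (0.109), heat shock 0.07 (0.140), autophagy and lysosome 0.02 (0.240) and mitochondrial-encoded proteins 0.03 (0.8). Vascular and blood markers did not pass: endothelial cells had a median of -0.03 (camera adjusted p = 0.465), pericytes and smooth muscle -0.12 (0.338), erythroid cells 0.12 (0.374) and globins 0.06 (0.746). The epithelial-mesenchymal transition list had a median of -0.02 (camera adjusted p = 0.519), with Itga5, an integrin, at 685 ± 11.9 and 534.8 ± 57.8 CPM as its 1 member past 0.05 adjusted over the list alone (edgeR, 0.0485). Matrix metalloproteinases had a median of 0.03 (camera adjusted p = 0.8), inflammatory cytokines 0.06 (0.829), neurons 0.26 (0.838) and angiogenic factors 0.08 (0.941). Adjusted over the list alone, edgeR called 0 members of the other 13 lists.

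Some of these 15 lists passed camera when 1 library was left out. Inflammatory cytokines passed in opposite directions, lower without shVec replicate 1 (mean -0.0193, camera adjusted p = 0.00278) and higher without shVec replicate 2 (mean 0.63, camera adjusted p = 0.000698), against a mean of 0.17 with all tumours. Heat shock genes passed higher without shNgb replicate 2 (mean 0.06, camera adjusted p = 0.00347) or shVec replicate 2 (0.15, 0.00236). Receptor tyrosine kinases and their ligands passed lower without shVec replicate 1 (-0.10, 0.0201) or 3 (-0.16, 0.00375), and Wnt targets without shNgb replicate 3 (-0.10, 0.0444) or shVec replicate 1 (-0.12, 0.0384). Oxidative phosphorylation passed higher without shNgb replicate 3 (0.04, 0.0444) or shVec replicate 1 (0.04, 0.0488), and autophagy and lysosome without shVec replicate 1 (0.06, 0.04999).

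Signs disagreed in 5 of these lists. Camera ranked the epithelial-mesenchymal list lower while its mean was 0.11, the metalloproteinase list lower while its median was 0.03 and its mean 0.01, and the neuron list lower while its median was 0.26 and its mean 0.02. The heat shock and mitochondrial-encoded lists ranked higher while their means were -0.004 and -0.02.

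The 8 lists with under 5 tested members were not tested. Their median log2 fold changes were 0.11 for adipocytes (4 members), -0.38 for astrocytes (3), 0.09 for keratinocytes (3), 0.22 for liver (1), 0.06 for mast cells (3), 1.15 for neutrophils (2), 0.05 for replication-dependent histones (4) and 0.04 for Schwann cells (4). Csf3r passed adjusted over the 2 genes of the neutrophil list alone (edgeR, 0.0058). The other, S100a9, had 83, 7 and 7 reads in shNgb and 24, 14 and 10 in shVec. The list scores in shNgb were 1.57, -0.53 and -0.09, so what S100a9 adds to this median rests on shNgb replicate 1.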

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

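Calls of genes were 0 in each direction with edgeR under RLE and upper quartile scaling (399 and 404 genes at an unadjusted p under 0.05), the strict filter (335), glmTreat (58) and each omission of 1 library (lowest 0 and highest 0, with 216 to 784 at an unadjusted p under 0.05), with limma-voom (428), and at thresholds of 0.01 and 0.1. Without the low-count filter edgeR called 3 lower (Ppp1r15a, adjusted p = 0.00805, Klf4, 0.016, and Nlrp1c-ps, 0.02, the latter chosen after its values were seen). DESeq2, also run without that filter, called 2 higher and 3 lower, and the cause was not tested. Over all settings the adjusted p ran from 0.00284 to 1 for Ppp1r15a, from 0.016 to 1 for Klf4, from 1.92e-08 to 1 for Hmgn2, from 7.58e-08 to 1 for Rpl17-ps10 and from 0.0443 to 1 for Col1a1. Replicate numbers were not treated as pairs: deviations from the group mean of same-numbered tumours correlated at 0.257, -0.145 and -0.0987 across genes, which are not independent replicates. With the replicate block edgeR called 1 lower (Rpl17-ps10, adjusted p = 0.0339) and 426 genes had an unadjusted p under 0.05. Ngb stayed negative, from -0.83 to -0.33 with 1 library left out, and had no value under the strict filter, which removed it.

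With an estimated correlation 0 lists were higher and 0 lower, and fry gave 0 and 0. With 1 library left out, 9 to 14 lists were higher and 7 to 11 lower. The filter was applied again in each omission, so these fits may also differ in the members of a list. Over 12 settings (the scalings, filters, limma-voom, the block and the omissions), 11 of the 23 lists kept call and direction wherever tested. These were hypoxia, interferon, glycolysis, immediate early, both MHC lists, cholesterol, stress response, fibroblast, mitosis and B cell. Under the strict filter the B cell list had too few members for a test, as had skeletal muscle, dendritic cells and neurons. All 12 settings used the preset correlation, so they leave that assumption untested. Calls ended without the filter for antioxidant targets (0.07), p53 targets (-0.02) and the neural list (-0.06), and with limma-voom for fibrillar matrix (0.19) and dendritic cells (0.48). Apart from the omissions, lists newly past camera were oxidative phosphorylation and receptor kinases (upper quartile), epithelial-mesenchymal (strict filter), and receptor kinases and Wnt targets (block).

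Lists that did not pass with all libraries changed direction in camera as follows, with mean log2 fold changes, whose sign can differ from that of the test (the cause was not tested): angiogenic factors with upper quartile scaling (0.0202) and the block (-0.000984), and globins (-0.59) and neurons (0.40) without the filter. With 1 library left out, lowest and highest means were -0.0193 and 0.63 for inflammatory cytokines (past camera in both, adjusted p = 0.00278 and 0.000698), -0.0735 and 0.10 for angiogenic factors, -0.12 and 0.15 for heat shock, -0.18 and 0.36 for neurons, -0.10 and 0.14 for globins, -0.0739 and 0.0797 for mitochondrial-encoded proteins, 0.01002 and 0.0414 for oxidative phosphorylation, -0.12 and 0.02 for endothelial cells, -0.073 and 0.0586 for metalloproteinases, and -0.0638 and 0.31 for erythroid cells. Of 96 named genes, 4 changed sign: Actn3 (-1.86 to 0.26) and Mylpf (-1.38 to 0.32) without shVec replicate 2, Xcr1 (-0.0426 to 0.56) without shNgb replicate 2 and Clec9a (-0.58 to 0.69) without shNgb replicate 3. Medians of all genes were 0.003 (TMM), -0.002 (RLE) and 0.02 (upper quartile). Ngb had 11 to 28 reads per library. Its summed reads gave a ratio of 0.648 with an interval of 0.436 to 0.957 from counting error alone, against 0.341 to 1.29 with the spread between tumours. The narrower interval treats reads as independent molecules, so how far depth limits the Ngb result was not settled.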

Other observations

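Among other globins, Hba-a1, a chain of haemoglobin whose reads are uncertain because the genome holds a near-identical copy, stood at 16.7 ± 5.77 CPM in shVec and 26.6 ± 8.27 CPM in shNgb (log2 fold change 0.67, SE 0.31, adjusted p = 0.9997 in edgeR). Adgb, which encodes androglobin, had 1, 0 and 0 reads in the shVec libraries and 0, 15 and 46 in the shNgb libraries, so all but 1 of its reads lay in shNgb 2 and shNgb 3. Mb, the oxygen store of muscle, had 0, 33 and 9 reads in shVec and 0, 10 and 0 in shNgb, while Cygb, which encodes cytoglobin, stood at 5.37 ± 2.21 CPM in shVec and 5.31 ± 2.06 CPM in shNgb (SD, n = 3, log2 fold change -0.01). Adgb, Mb and Cygb were chosen after their values were seen.

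The tests below on single tumours, endothelial markers, summed copies and Xist, and the split of the tumours for genes, were chosen only after the result was seen, and the split for lists was not. The 10 splits of the tumours into 3 and 3 are too few for a share under 0.05. For genes past an adjusted p of 0.05 in edgeR the real split gave 0 and the highest of the others 38, and with a real count of 0 each of the 10 gives as many whatever the data. For lists past camera at the preset correlation the real split gave 23 and the highest of the others 18, so 1 of 10 gave as many, and with an estimated correlation each of the 10 gave 0. The size of the mean log2 fold change was 0.771 for the interferon list in the real split and up to 1.31 in the others, with 3 of 10 as large, and 0.461 for the hypoxia list against up to 0.368. At an unadjusted p under 0.05 the real split had 392 genes, and 7 of the 10 splits, the real one included, had as many or more. The split that called the 38 genes, picked after its values were seen, parts shVec 1, shVec 3 and shNgb 2 from the rest. It had 1835 at an unadjusted p under 0.05, but 9 lists against 23. Being picked as the highest of the splits, it does not by itself show a structure of the samples other than the group. On the first principal component, the main axis of variation in log2 CPM (36% of the variance), the groups overlapped. The shVec tumours stood at -32.9, 16.6 and -18.3 and the shNgb tumours at -11.6, 5.24 and 40.9. The largest variation among the tumours thus did not follow the group, and what lies behind it was not tested.

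The first pattern is the shift of hypoxia genes down and of interferon and T cell genes up. The difference in list score without shNgb replicate 3 was -0.314 for hypoxia (SE 0.174, -0.52 with all tumours) and 0.427 for interferon (SE 0.538, 0.787 with all tumours), so whether this tumour carries the shift cannot be told apart from a shift shared by the group at this spread. A larger share of all host cells in shNgb tumours would raise endothelial markers along with T and NK cell markers. The T and NK cell difference exceeded the endothelial one (-0.0616, SE 0.0834) by 0.844 with an SE of 0.844, too wide a spread to decide. An effect of the hairpin, a difference in tumour size or in immune cells that entered by chance stay open, as none was tested.

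The second pattern is the exchange between near-identical copies. Rpl17 stood higher and Rpl17-ps10 lower in shNgb (log2 fold changes 1.02, SE 0.26, and -1.06, SE 0.16), and their summed reads differed by -0.048 (SE 0.0685), which is consistent with reads shared between the copies. Hmgn2 and Gm10282 summed to 0.12 (SE 0.10), against 0.40 with Gm10282 unchanged, but the interval of Gm10282 alone (-0.46, 95% interval -1.06 to 0.13) holds both 0 and the -0.68 that losing the reads gained by Hmgn2 would give, so a change of Hmgn2 and an exchange of reads cannot be told apart. The pairs were picked because they moved. A strain or tumour variant against the reference, which could shift reads from one copy to the other, stays open because sequences of reads were not analysed here.

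The third pattern, noticed after the values were seen, is Xist, the RNA of the inactive X chromosome, at 29.7 ± 5.68 CPM in shVec and 42.9 ± 9.92 CPM in shNgb (log2 fold change 0.53, SE 0.20, adjusted p = 0.9997 in edgeR). A hypothesis is that Xist may come in part from immune cells of female hosts, as the 4 Y-linked genes examined had 0 reads in every library and the sex of the mice was not used here. Over the 6 tumours Xist followed the macrophage score with r = 0.861 (exact permutation p = 0.0208, adjusted 0.0417 over 6 relations) and rho = 0.829 (exact permutation p = 0.0583, adjusted 0.117), but r was 0.644 without the 2 tumours farthest from the median, shNgb 3 and shVec 1, so the relation rests in part on them. Xist also followed the hypoxia score with r = -0.887 (exact permutation p = 0.00417, adjusted 0.025; rho -0.943, exact permutation p = 0.0167, adjusted 0.1; r -0.953 without those 2), so a change within the tumour cells stays open. The other 4 relations were MHC class II (r 0.881, rho 0.829), interferon (0.871, 0.6), T and NK cells (0.759, 0.486) and endothelial cells (-0.275, -0.314), with exact permutation p for r of 0.00833, 0.0333, 0.0861 and 0.588 (adjusted 0.025, 0.05, 0.103 and 0.588) and for rho of 0.0583, 0.242, 0.356 and 0.564 (adjusted 0.117, 0.362, 0.427 and 0.564); without those 2 tumours r was 0.827, 0.437, 0.585 and -0.919.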
